A study of Vanderwaltozyma polyspora with 2 samples.

How the data were processed

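Small RNAs that co-purified with a recombinant yeast Argonaute were sequenced from 2 preparations of the same protein, 1 library from soluble protein and 1 from crystals. The protein was a fragment of Kluyveromyces polysporus (Vanderwaltozyma polyspora) Ago1 from residue 207 to residue 1251, made in Escherichia coli. Argonautes are proteins that hold a short guide RNA. Per the labels' protocols, RNA was taken from the protein with phenol, made into small-RNA libraries and size selected from 8 to 24 nt. The groups come from the form of the protein given in the labels. Each group has 1 library.

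Each file deposited by the authors lists distinct 36 nt reads with a whole-number count of each. The deposited counts are not normalised. The tools the authors used, any filter and the reads they left out are not given in the sources used here. Every listed read held the first 8 nt of a 3' adapter, and no insert was longer than 24 nt, so the lists may be limited to such reads. No base qualities are in the files. Reads are written in DNA letters, with T for U, and sequences are printed that way.

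The insert was taken as the bases before the first 8 nt of the adapter, whose sequence was read off the reads. Inserts of 8 to 24 nt entered the comparisons. Shares of counts carry exact Clopper-Pearson intervals at 95%. Ratios of shares carry the interval of the exact binomial distribution of the counts. These intervals cover counting error only: reads copied by PCR are not independent molecules, and the difference between libraries made separately is not in them. With 1 library per group no test was made and no p-value is given. The comparisons are between these libraries, and preparation, sequencing and protein form cannot be separated.

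Inserts of 14 nt or more were compared, by perfect match on both strands, with sequences entered by hand from textbook knowledge before the data were examined: E. coli 16S, 23S and 5S rRNA, 12 tRNAs, lacI, an origin of replication of the ColE1 type, and yeast SMT3, a fusion tag used in expression vectors. The labels do not say which vector was used. Because lacI is also a chromosomal gene, its matches do not name a source. Positions are counted from the first base of each entered sequence. An error in an entered sequence lowers its match share. The entered 16S, 23S and lacI sequences differ from a BL21(DE3) genome at a few sites, so their shares are lower limits in this respect; SMT3 and the ColE1-type origin are not in that genome and were not checked. The kanamycin resistance gene kanR, the T7 terminator and a second plasmid origin segment were added after the data were seen. Of the 14 nt words, 8 occur in more than 1 class, and an insert was given to the first class in the list. The 2 origin segments overlap in this way. No genome was used for matching, so inserts from Ago1 itself and from the rest of the E. coli chromosome count as unmatched.

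A 5' end is the first 12 nt of an insert of 12 nt or more. Except where they are said to be chosen after their values were seen, the sequences named in the text follow a rule set before the data were examined: the 10 most abundant inserts of 10 nt or more in each library, the 5' ends with the 5 largest folds in each direction among those with at least 100 reads in both libraries together, and the 2 most abundant inserts of each library in each RNA class. Naming a sequence for its fold, or for its abundance in 1 library alone, favours a larger ratio in that direction. The intervals do not allow for this. A pseudocount of 0.5 reads was used to rank folds. A fold against 0 reads is given as a bound, with 3 reads as the floor. Sequences of unknown origin seen in the crystalline library alone are not printed.

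Alternatives covered the counting unit, abundant sequences, length range, adapter match of 6 nt or 12 nt, ambiguous bases, match length, mismatches, depth, pseudocount and read minimum. Those chosen after seeing the data were leaving out inserts that hold the end of the 5' adapter, adding vector references, and leaving out the most abundant sense 5' end of SMT3 or of lacI. An extension of the SMT3 sequence from overlapping inserts was also tried under a range of settings; the joins were ambiguous and depended on the settings, and it is not reported. The second condition of the test of whether crystal RNAs lack nucleotides at their 5' end is not reported here.

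The functions were tested on simulated data. In 200000 simulated reads per library, first-nucleotide and length shares came back within 0.14 percentage points. Among 3200 simulated 5' ends, of which 200 had a changed level, the median log2 fold came back within 0.018 of that simulated. The interval held the simulated fold in 93.0% of the changed ends. The simulated ends had many reads in both libraries, so folds of ends with few or no reads in a library were not tested. Nor was the scaling of folds to library size tested. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.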

Results

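The soluble library held 20750634 reads and the crystalline library 20461149. Inserts of 8 to 24 nt made up 11484524 of the soluble reads (55.3%) and 12456838 of the crystalline reads (60.9%). There were no replicates, so each value below describes 1 library, and intervals cover counting error only.

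The first comparison asks whether RNAs of the same size were bound in both preparations. From 6 nt upwards, both libraries had local maxima at 7, 12 and 17 nt. Longer inserts took a larger share of the crystalline library. Inserts of 14 to 24 nt were 17.0% of those of 8 to 24 nt there (95% interval 17.0 to 17.1) and 11.4% in the soluble library (11.4 to 11.5). Inserts of 12 nt were 18.03% (18.01 to 18.05) in the crystalline and 15.5% (15.5 to 15.5) in the soluble library. Inserts of 8 and 9 nt went the other way, with 46.3% in the soluble and 35.6% in the crystalline library.

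**Figure D1:**
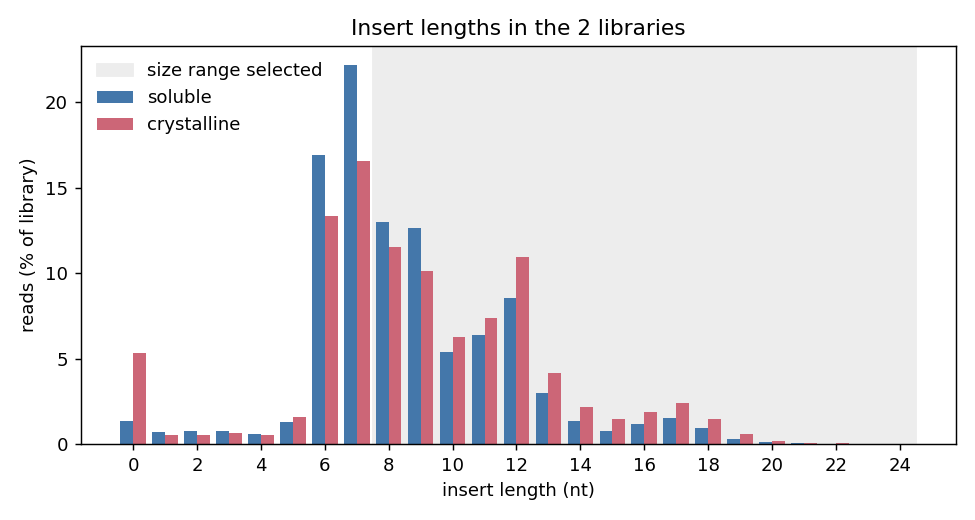
Insert length in nt against the percent of all reads of each library, with soluble bars in blue and crystalline bars in red; the shaded area is the size range selected. At 12 nt the soluble library held 8.58% and the crystalline library 10.98% of its reads.

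The second comparison asks which nucleotide stood at the 5' end, which in Argonautes sits in a pocket of its own. Counted over reads, U was the most frequent first nucleotide in both libraries, at 57.5% of soluble reads (95% interval 57.4 to 57.5) and 40.2% of crystalline reads (40.2 to 40.2). A was first in 17.8% of soluble reads (17.8 to 17.8) and 37.8% of crystalline reads (37.8 to 37.9). G was rare at this position, at 5.87% and 6.53%, against 18.3% and 22.6% over all positions of the same inserts. Over distinct sequences it was first in 11.7% and 13.1%, against 19.8% and 23.1%. C was first in 18.9% and 15.4%. In the crystalline library this order depended on the counting: A was ahead of U over distinct sequences, at 37.96% against 29.1%, without the 10 most abundant sequences, at 39.9% against 38.3%, and in inserts matching rRNA or tRNA, at 30.96% against 29.2%. A was also ahead there at 8, 10, 11, 15 and 21 to 24 nt. In the soluble library U stayed ahead of A in each of these. At every length from 8 to 24 nt the crystalline library had the lower U share and the higher A share. Counted over distinct sequences, the difference in A was 12.04 percentage points where it was 20.02 over reads, and that in U was -10.00 where it was -17.2.

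**Figure D2:**
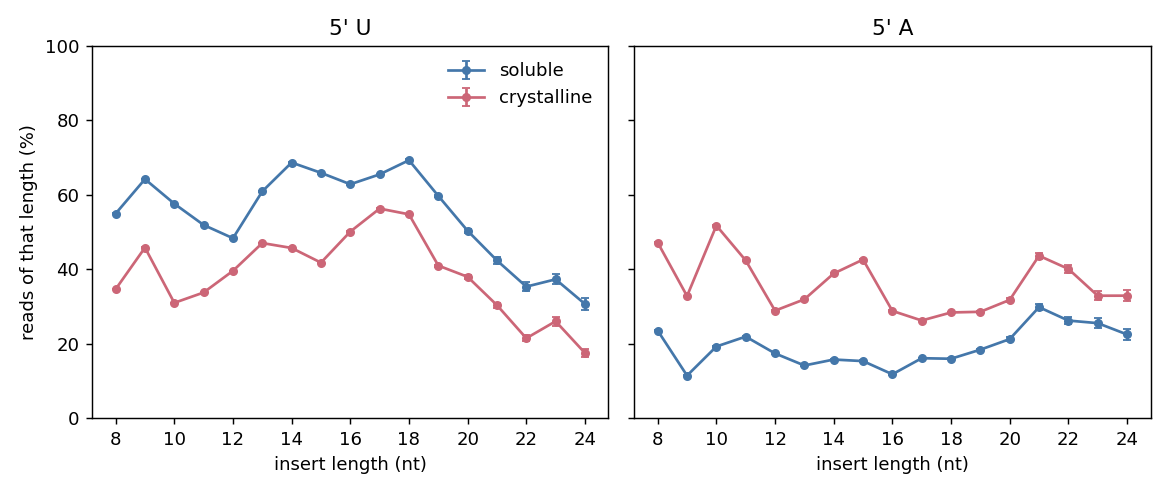
Percent of reads that begin with U (left) or A (right) against insert length in nt, with 95% Clopper-Pearson intervals as bars, soluble in blue and crystalline in red. At 10 nt, A was first in 19.3% of soluble and 51.8% of crystalline reads.

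Downstream of the first nucleotide no single base differed between the libraries as much as A or U did at position 1. Differences remained there: U at position 5 was 34.5% in the soluble and 26.4% in the crystalline library, and U at position 9 was 32.8% and 25.6%. Over all positions of the same inserts U was 32.7% and 27.0%, so most of these gaps lay in the overall composition. A plus U made up 60.9% of positions 2 to 10 in the soluble library and 58.4% in the crystalline library. In this sum opposite shifts of A and U cancel. A was frequent at position 2, at 37.9% of soluble and 41.5% of crystalline reads, against 27.7% and 31.5% over all positions. Over distinct sequences this excess was not seen, with A at position 2 in 27.1% and 28.1%, against 27.4% and 29.6% over all positions. G at position 4 reached 27.3% in the soluble library and 36.7% in the crystalline library. In inserts of 12 to 18 nt it was higher in both and differed less, at 40.5% and 44.9%, against 21.2% and 24.1% over all positions. Over distinct sequences G at position 4 was 22.1% and 26.4%, against 19.8% and 23.1% over all positions, a smaller excess than over reads. Counting each short sequence once narrows any base preference, so this does not show that the excess lay in a few abundant sequences. Where inserts matched the vector genes, the base 1 nt before the insert was U in 19.5% of soluble and 28.4% of crystalline reads, and the first base of the insert was U in 63.9% and 49.1%; the entered genes hold 24.6% U over both strands.

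The third comparison asks which RNAs the inserts came from. Ribosomal RNA, the bulk of the RNA of a bacterium, was a small part of the inserts of 14 to 24 nt in both libraries. Shorter inserts were not given a class, so their rRNA share was not measured. Inserts of 10 to 14 nt equal to the end of 16S rRNA numbered 55779 in the soluble and 5424 in the crystalline library. The rRNA matches among inserts of 14 to 24 nt numbered 4661 and 9673. Of inserts of 14 to 24 nt, 0.355% of soluble reads (95% interval 0.345 to 0.365) and 0.456% of crystalline reads (0.447 to 0.465) matched rRNA, and 0.0449% and 0.0837% matched the entered tRNAs. Sequences that expression vectors carry were more frequent. The gene of the lac repressor, lacI, was matched by 12.1% of soluble reads (12.1 to 12.2) and 9.94% of crystalline reads (9.90 to 9.98). Most of this difference lay at a single sense 5' end, at position 422, which held 2.42% and 0.618% of reads. Without it lacI was matched by 9.72% and 9.32%. The ColE1-type origin was matched by 1.29% and 1.71%, and SMT3 by 1.71% and 3.63%. Together these 3 sequences made up 15.1% of soluble and 15.3% of crystalline reads. Much of this lay in abundant sequences: over distinct sequences they were 4.13% and 3.20%, and rRNA 0.770% and 1.09%. The kanamycin resistance gene, added after the data were seen, was matched by 11.3% and 11.2%. With the added sequences, 31.1% of soluble and 30.7% of crystalline reads matched vector sequences, and 68.5% and 68.8% matched nothing entered.

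The vector genes were matched on both strands, the ColE1-type origin mainly on the antisense strand, and rRNA mainly on the sense strand. The antisense strand gave 44.9% of lacI reads in the soluble library (95% interval 44.6 to 45.1) and 52.0% in the crystalline library (51.8 to 52.2). For kanR it gave 46.5% and 50.5%, and for the ColE1-type origin 83.9% and 76.7%. The T7 terminator, which was added later, was mainly matched in sense, by 0.801% of soluble reads against 0.0335% in antisense. The added origin segment was also mainly matched in sense, by 3.37% of soluble reads against 0.423% in antisense, and by 3.12% of crystalline reads against 0.571%. Where they overlap, the entered origin sequences run in opposite directions. AAAGAGTTGG extends into the antisense strand of the ColE1-type origin and lies on the sense strand of the added segment. If this direction holds beyond the short stretch they share, both origin entries were mainly matched on the same strand. Of rRNA reads, 2.94% were antisense in the soluble library (2.47 to 3.47) and 1.67% in the crystalline library (1.43 to 1.95). SMT3 differed most between the libraries among these classes. Its antisense share was 51.6% in the soluble and 20.9% in the crystalline library. Sense inserts of SMT3 were 3.46-fold more frequent in the crystalline library (3.39 to 3.53), and antisense inserts 0.858 times as frequent (0.838 to 0.879). A single 5' end at position 111 held 66.9% of the crystalline and 40.3% of the soluble sense reads of SMT3. Without it the ratio of sense inserts was 1.92 (1.86 to 1.97). Over distinct sequences the SMT3 share was 0.790% in the soluble and 0.605% in the crystalline library, the opposite order.

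**Figure D3:**
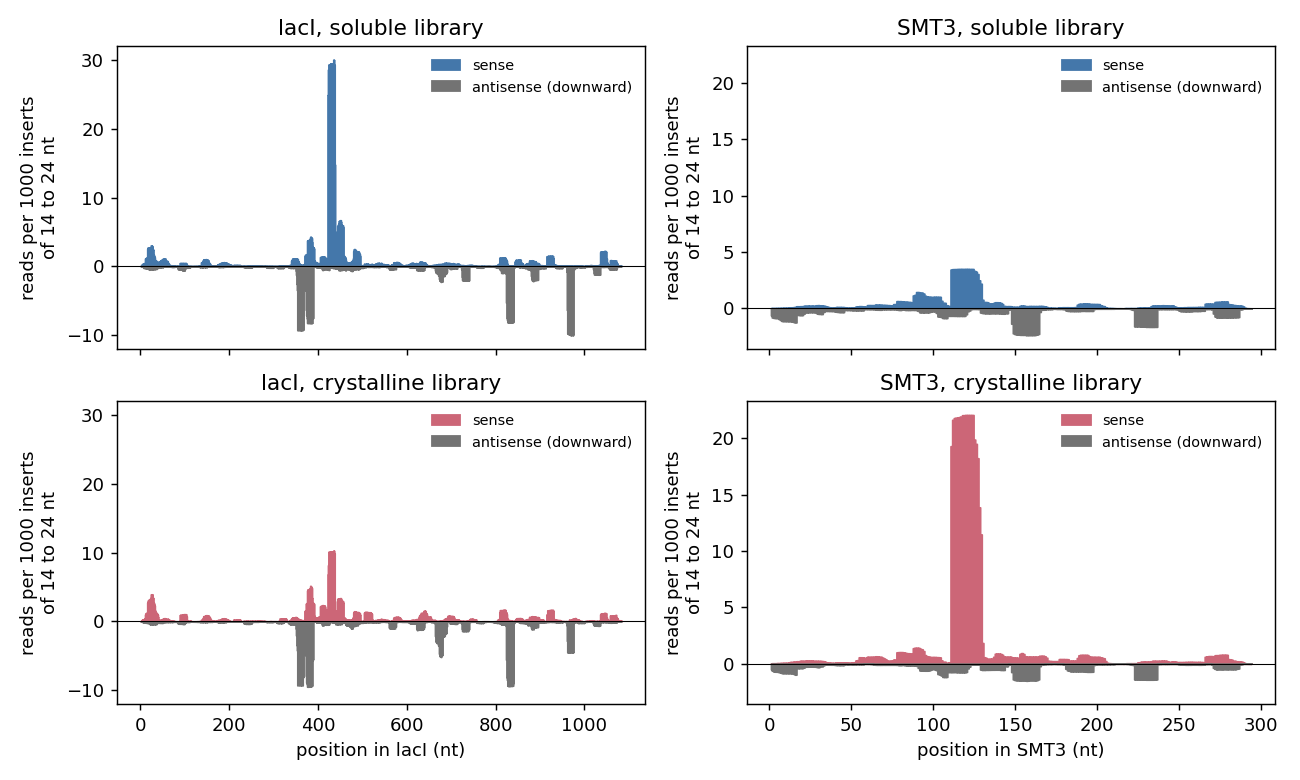
Reads covering each position of lacI (left) and SMT3 (right), per 1000 inserts of 14 to 24 nt, in the soluble (top) and crystalline (bottom) library; sense reads point up and antisense reads, in grey, point down. The highest sense peak of SMT3 reached 3.51 in the soluble and 22.1 in the crystalline library, and that of lacI 30.1 and 10.3.

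The most abundant inserts of 10 nt or more were largely shared. The insert TAAGACACGACT, antisense to the ColE1-type origin at positions 255 to 266, ranked 1 in both, with 1.30% of soluble and 1.51% of crystalline inserts. CAGGAACACTGC, antisense to kanR at positions 373 to 384, ranked 2 in both, with 0.885% and 1.16%. TTGGTTCAAAGA, the start of the added origin segment, had 0.587% and 1.01%. TCAACCAAACC, which longer inserts extend into antisense kanR, had 0.747% and 0.360%. TTTGGTTGATG, extended into sense kanR, had 0.503% and 0.386%. GAAGTTATTAGG had 0.434% and 0.403%, and AATGGTTTCTC 0.411% and 0.392%; longer forms of both matched nothing entered. GGAACATTAGTG, which equals antisense lacI at positions 420 to 431, was 2.26-fold higher in the soluble library (95% interval 2.23 to 2.29). Of 101 longer reads that start with it, 50.5% matched antisense lacI. TAATAACTTC, with no match, was 3.12-fold higher there (3.06 to 3.18). CGCTGGATGACC, which equals lacI at positions 380 to 391, was 3.15-fold higher in the crystalline library (3.09 to 3.21). Of 301 longer reads that start with it, 50.8% matched nothing entered.

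AAAGAGTTGG was 30.9-fold higher in the crystalline library (95% interval 29.9 to 31.9), with 125809 reads against 3752, and AAAGAGTTGGT was 29.04-fold higher (27.8 to 30.3). This sequence occurs in both origin segments. CACCTCCTTA, which equals the last 10 nt of 16S rRNA, was 11.8-fold higher in the soluble library (11.4 to 12.2), with 40886 reads against 3747. In lacI, the insert CTAATGTTCCGGCGTT was 1.72-fold higher in the soluble library (1.68 to 1.76), and CTAATGTTCCGGCGTTA, 1 nt longer, was 10.99-fold higher there (10.3 to 11.7). TCAGCCCACTGACG, antisense to lacI, was 1.30-fold higher in the crystalline library.

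Within the other classes, the leading SMT3 inserts CAAGATCAAAAAGACCACT and CAAGATCAAAAAGACCA, both from position 111, were 8.94-fold (95% interval 8.53 to 9.39) and 9.96-fold (9.24 to 10.7) higher in the crystalline library. TCAGGGGTCTGATC, antisense to SMT3, was 1.31-fold higher there. At the ColE1-type origin, CTTCGGGAAGCGTGGC and TAAGACACGACTTATCG were 3.48-fold and 2.40-fold higher in the crystalline library, and TATCGCCACTGGCA was 1.98-fold higher in the soluble library. The initiator tRNA inserts CGCGGGGTGGAGCAGC and CGCGGGGTGGAGCAGCCT, which start at its first base, were 6.67-fold (4.65 to 9.85) and 10.4-fold (6.49 to 17.6) higher in the crystalline library. GTCCCCTTCGTCTAGAG, from the first base of a glutamate tRNA, had a ratio of 1.42 (0.941 to 2.15), not distinguishable from 1 at this depth.

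For 16S rRNA, CTCAGATTGAACGCTG at positions 23 to 38 was 1.37-fold higher in the crystalline library (95% interval 1.25 to 1.51), and TGAAATGTTGGGTT had a ratio of 1.08 (0.952 to 1.22). For 23S rRNA, TTCTGAATGGAAGGGC and CTCGCTGTGAAGATGCA were 6.90-fold (4.60 to 10.7) and 12.4-fold (6.56 to 26.5) higher in the crystalline library. TTCCTTGTCGGGTA and TTAAAAACACAGCA were 9.76-fold (4.20 to 27.8) and 2.47-fold (1.47 to 4.27) higher in the soluble library. In that order, these rest on 202 against 27, 135 against 10, 54 against 6 and 50 against 22 reads. Each was named for its abundance in the library where it was higher, which favours the direction seen. The first bases of 5S rRNA, as TGCCTGGCGGCCGTAGC and TGCCTGGCGGCCGTAG, were 2.68-fold (1.76 to 4.17) and 1.87-fold (1.08 to 3.33) higher in the soluble library.

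The last comparison asks how far the same RNAs were in both preparations. The soluble library held 144745 distinct 5' ends and the crystalline library 202194, of which 55416 were shared. At equal depth the crystalline library had 163317. Shared ends held 97.1% of soluble and 94.6% of crystalline reads. The 10 most abundant ends took 18.3% and 17.3%. Across 5434 ends with at least 100 reads in total, Spearman's rho between the libraries was 0.508; ends are not independent replicates. Of the 100 most abundant ends of each library, 59 were the same.

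The largest folds were at ends with few or no reads in 1 library. These ends were named for the size of their folds, which favours extreme values, and the intervals do not allow for that choice. The 5 ends highest in the crystalline library had 605 to 1519 reads there and 0 in the soluble library, at least 144-fold to at least 361-fold higher against a floor of 3 reads. Their G plus C content ranged from 58.3% to 100%, and they matched nothing entered. It is not known whether they come from the protein preparation or from another organism. In the other direction, TAGCGAAAGCTA had 103 soluble reads and 1 crystalline read, a ratio of 145 (95% interval 25.4 to 5766). CAGCCATCATTT, extended into 23S rRNA, was 76.5-fold higher in the soluble library (20.7 to 640). CGATATTATTGA, extended into sense SMT3, was 45.9-fold higher (15.2 to 226), with 98 reads against 3. CAATACTATTGA and TTGACAAACCAT were 44.9-fold and 43.2-fold higher there and matched nothing entered.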

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

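The test on 7 nt inserts was written before its result was seen, and that on 6 nt inserts after the 7 nt result and before its own. The insert ACGACT and the values on the end of 16S rRNA were chosen after they were seen. Inserts below the selected size range were frequent. Those of 6 and 7 nt made up 39.1% of soluble and 29.9% of crystalline reads, although the labels give a lower size limit of 8 nt. If they were 5' parts of the longer inserts, counts of 7 nt inserts across all 7-mers would follow the starts of inserts of 12 to 24 nt more closely than the ends, by 0.05 or more in Spearman's rho. The difference was 0.0235 in the soluble and 0.0338 in the crystalline library, above 0 and below that limit. For 3' parts the difference, taken the other way round, was at most -0.0235. For 7 nt inserts, neither end alone accounts for them under these limits, and a mixture of both stays open. For 6 nt inserts, compared in the same way across 6-mers, starts exceeded ends by 0.107 in the soluble library (resampled interval 0.0820 to 0.129) and by 0.0672 in the crystalline library (0.0473 to 0.0870). This passes the limit for 5' parts in both libraries, though the crystalline interval reaches below it, and argues against 3' parts alone, where the higher value was -0.0672. A first-nucleotide preference shared by short and long inserts would also raise the correlation with starts, and was not separated from it. Single sequences can differ from this: ACGACT, the last 6 nt of TAAGACACGACT, had 134513 crystalline and 2328 soluble reads, 53.3-fold more relative to inserts of 8 to 24 nt (95% interval 51.1 to 55.5). No biological explanation was tested.

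The last 10 nt of 16S rRNA, a stretch shorter than the length used for matching, were read 40886 times in the soluble and 3747 times in the crystalline library. Among all 1533 windows of 10 nt in 16S rRNA the median was 0 reads in both libraries, and this window ranked 1 in the soluble and 2 in the crystalline library. Windows of other lengths were not counted. Inserts below 14 nt were not given a class, so a source in 16S rRNA was not established for them. Inserts equal to the last bases of 16S rRNA, up to base 1542, were higher in the soluble library by a factor that varied with length. It was 11.1 at 8 nt (95% interval 10.7 to 11.5), 3.64 at 9 nt (3.50 to 3.78), 11.8 at 10 nt and 9.83 at 11 nt. It was 7.80 at 12 nt (6.67 to 9.16) and, on 88 against 5 reads, 19.1 at 13 nt (7.88 to 60.2). At 14 nt there were 3 reads against 1, a ratio of 3.25 (0.261 to 171), not distinguishable from 1.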

How the results depend on the processing

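No paired analysis was possible because each group has 1 library. At this depth the counting intervals are narrow, so small shifts pass them; what limits the comparison is the lack of replicates. Values are crystalline minus soluble, in percentage points unless stated, and causes were not tested unless given. The A and U differences at the 5' end kept their direction under all alternatives run. For 5' A the values were 14.8 with 12 to 18 nt inserts, 12.04 over distinct sequences, 18.2 in rRNA or tRNA inserts and 19.6 without the 10 most abundant sequences. For 5' U, in that order, they were -11.6, -10.00, -16.0 and -16.1. A plus U at positions 2 to 10 gave -2.32 with 12 to 18 nt inserts, -2.53 over distinct sequences and -2.37 without the 10 most abundant. The share of 14 to 24 nt inserts gave 5.53 with an adapter match of 6 nt, 5.90 over distinct sequences and 5.70 without the 10 most abundant. Leaving out ambiguous bases removed no insert of 8 to 24 nt and tests nothing.

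The class shares depended on the setting. Shares over distinct sequences were not taken at equal depth, so a reversal there is not read as a change of level. For SMT3, 1.91 became 2.60 at 16 nt, 4.79 at 18 nt and 4.97 at 18 nt with 1 mismatch. It became 0.328 without its most abundant 5' end (chosen after seeing the data) and, reversed, -0.185 over distinct sequences. For lacI, the origin and SMT3 together, 0.132 became 0.468 at 16 nt, 2.98 at 18 nt and 3.10 at 18 nt with 1 mismatch. It became 1.93 without the most abundant sense 5' end of lacI (chosen after seeing the data). It reversed to -0.929 over distinct sequences and to -0.377 with the added references (chosen after seeing the data), so no direction is read. For rRNA, 0.101 became 0.155 at 16 nt, 0.168 at 18 nt, 0.196 at 18 nt with 1 mismatch and 0.322 over distinct sequences. With full sequences in place of 5' ends, the crystalline reads shared with the soluble library were 91.4%, and the top 10 share differed by -0.893. With inserts of 14 nt or more, 3 of the 10 named ends reached 100 reads, all in the main direction. The log2 folds of named ends moved by 0.5 or more in 10 of 10 ends with a pseudocount of 5, in 1 of 3 with inserts of 14 nt or more and in 0 of 10 without 5' adapter inserts, and none of these reversed; a read minimum cannot move them. Which ends were largest depended on the setting: 6 of the 10 stayed among the largest with 20 reads as minimum, 6 with a pseudocount of 5 and 2 with inserts of 14 nt or more. With a pseudocount of 5 the highest log2 fold went from 11.08 to 7.76 and the lowest from -6.60 to -4.66.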

Other observations

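Of the tests here, those on abundant sequences and on rRNA strands were chosen after the result was seen; the others were written before it. The inserts TAACTGATT and CTAATGTTC, chosen after their values were seen, were the most abundant of 9 nt in the soluble library, at 3.69% and 1.77% of inserts, and were 2.24-fold and 2.56-fold higher there than in the crystalline library. AACTGATT, the first of these without its 5' nucleotide, was 3.08-fold higher in the crystalline library (95% interval 3.02 to 3.14). Reads in 5' ends not seen in the soluble library were 5.35% of crystalline reads, with a G plus C content of 49.1% against 42.2% in shared ends. Inserts of 0 nt, adapters joined directly, were 1.33% of soluble and 5.36% of crystalline reads.

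The lower 5' U and higher 5' A share in the crystalline library was set against technical explanations. A few abundant sequences alone are argued against. The difference in A was 12.04 percentage points over distinct sequences and 19.6 without the 10 most abundant. Distinct sequences were not taken at equal depth. Misread copies of abundant sequences may be among them, which limits the value of 12.04. Miscalled first bases are argued against: where the vector gene has T, the share read as A differed by 0.0160 percentage points. A different mix of source RNAs is argued against as the whole cause, as A was higher by 5 percentage points or more in 8 of 8 vector gene strands, though U was 1.52 percentage points higher, not lower, on the sense strand of lacI. The hypothesis that crystal RNAs may lack nucleotides at their 5' end is not argued against, though only part of its planned test is given here. The condition given, set at more than 50%, was met: inserts were shorter in crystals at 532 of 732 shared 3' ends, or 72.7%. These are 3' ends in the vector genes with at least 50 reads in both libraries. The median shortening over all 732 was only 0.0951 nt, and how much of the difference this accounts for was not measured. Crystalline inserts were not shorter in general. Those of 14 to 24 nt were 17.0% of inserts of 8 to 24 nt, against 11.4% in the soluble library. Library preparation and protein form are confounded, so a biological difference between soluble and crystallised protein stays untested.

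Inserts matching vector genes on both strands were weighed next. Chance matches are argued against: reads matching the reversed vector genes were 0% of those matching the antisense strand. A library preparation that copies either strand is argued against by the antisense share of rRNA inserts, 2.09% against 48.4% for lacI, kanR, SMT3 and the ColE1-type origin together. Inserts matching tRNA, few in number, were antisense in 80 of 590 soluble and 161 of 1776 crystalline reads. That is above the rRNA share and below the share of the pool. The T7 terminator, which is not in that pool, was mainly sense, so the pattern does not extend to every vector sequence entered. The added origin segment, also outside the pool, was mainly sense too. In the stretch that the origin entries share, the segment's sense strand is the antisense strand of the ColE1-type origin. That stretch is short, with at most 8 words of 14 nt shared between classes. If the direction holds beyond it, both entries were mainly matched on the same strand. Their strand names would then reflect only how they were entered. No biological explanation was tested.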
